A study of Pimephales promelas with 32 samples.

How the data were processed

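The samples were ovaries of 32 female fathead minnows (Pimephales promelas, a small freshwater fish widely used in toxicity testing), held for 96 h in flowing lake water without bisphenol A (controls) or with it at 5 concentrations, the lowest 0.01 µg/L and the highest 100 µg/L. Bisphenol A is a plastics monomer that binds estrogen receptors weakly. RNA of each ovary was labelled with the dye Cy3 and hybridised to 1 array of a custom Agilent 15K design, so 1 array stands for 1 fish and no sample was pooled. The control and the 1.0 µg/L group held 6 fish each and the other 4 groups 5 each. The fish came from 18 tanks, 3 per concentration, and per the labels' protocols fish were added in a stagger by replicate tank. The arrays lay on 4 slides of 8. The labels also gave each fish's body and gonad weight, estradiol and testosterone production by ovary tissue held in culture, and plasma vitellogenin. Gonad weight as a percent of body weight is called the gonadosomatic index. Vitellogenin was missing for 1 fish, BPA 10 replicate A. The companion zebrafish arrays were not analysed here.

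The scanner files hold spot intensity values that the authors extracted with Agilent Feature Extraction, protocol GE1-v5_95_Feb07 and program version 9.5.1.1 per the file headers. The processed signal was detrended across the surface of each array, by subtraction and by a multiplicative surface, per the file headers, which record no step between arrays. In the files of all 32 arrays the background subtracted from the mean spot intensity was the fitted spatial surface. The files also give a mean spot and a local background intensity, and flags for outlier spots, saturation and signal well above background. The submitters' processing notes name Agilent Feature Extraction 9.5 and R 2.10.1. The authors deposited in addition a value table on a log2 scale. Its columns correlated with the log2 mean spot intensity of the same array at r = 0.988 to 1.000 across probes, and their medians lay between 6.12 and 6.78. How the authors scaled that table is not given in the sources used here. Its 75th percentiles lay at 8.95 to 8.97 in the arrays at 10 µg/L and at 9.24 to 9.65 in the other groups, most of which overlapped. It was used only as an alternative.

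Of 15744 features per array, 15208 were not control spots. The main values were log2 of the processed signal minus the 75th percentile of each array. Outlier spots were set to missing, 4701 in all, and saturated spots were kept. A probe entered the tests if it was well above background on at least 5 arrays and had at least 3 unflagged spots in every group. This left out 3424 probes for the background condition and a further 116 for flagged spots, so that 11668 were tested. The 75th percentile of the processed signal ranged from 184.5 to 1807 between arrays and 47.3% to 79.0% of probes were well above background. The number of arrays limits the precision. The median 95% interval of a log2 difference between a concentration and the control reached 0.91 to 0.96 on either side.

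Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The comparisons were a moderated F test over the 6 groups, the mean of the exposed groups against the control, a slope on the dose score (the rank of the concentration, with the control at 0), and each concentration against the control. Each of the 4 fish measures was fitted as a slope within dose groups, with the hormones and vitellogenin on a log2 scale. The fish measures themselves were tested against the control with 2-sided exact permutation tests, adjusted over 20 comparisons. Their trends over the dose score used 100000 permutations of Pearson's r and Spearman's rho, adjusted over 4 measures. These steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The tests, the design and the alternatives below, apart from those said to be added later, were chosen before the data were examined.

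The fits were tested on simulated arrays in which 50 probes per fold size were changed by known amounts. For BPA 10 against control, 16% of 2-fold, 40% of 3-fold and 46% of 4-fold changes were recovered among 11668 probes. For the mean of the exposed groups the shares were 20%, 70% and 80%, and for the dose trend 32%, 56% and 62%. For the moderated F test they were 16%, 32% and 58%. For the slope on the gonadosomatic index, with the fold taken over the full range of the index, they were 0%, 20% and 32%.

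The rule for naming probes took, among those past the threshold, the largest positive and negative changes. The files give each probe an identifier and a sequence of 60 bases but do not pair it with a gene name. The reference table of Pimephales promelas genes, assembly fPimPro1.hap1.1, holds symbols and no sequences, and 0 of the design names matched a symbol. Therefore only 2 probes that rose and 2 that fell with the gonadosomatic index are named, and the gene lists chosen beforehand, with their set tests, could not be run.

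Alternatives were quantile normalization, normexp background correction with offset 50, the authors' value table, no filter and a filter on all 32 arrays, slide, tank, tank number or array letter as a block, the gonadosomatic index as a covariate, array weights computed by limma, a fit of only the groups compared, other dose scores, measures on the other scale (log2 or untransformed), no dose-group terms, tank means and log2 values for the fish measures, and leaving out each fish. Array brightness (the log2 75th percentile) as a covariate, the value table on each array's own percentile, a fit without control replicates D and E, tests within tank numbers and trends without each fish were added after the data were examined. The tank block was a random effect, which used statmod 1.5.0. Tank number marks a shared start of exposure per the labels' protocols, so it was taken as a pairing of fish across groups. Fish of different groups with the same tank number had deviations from their group means that correlated at r = 0.031 on average over 141 pairs, against -0.015 over 285 other pairs.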

Results

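Ovarian transcripts and 4 fish-level measures were compared across 6 concentrations of bisphenol A in 32 fathead minnows. The study asked at which concentrations, if any, transcripts of the ovary respond after 96 h. Arrays differed in brightness within groups: the 75th percentile of the processed signal averaged 943 ± 590 (SD, n = 6) in the controls and 513 ± 93.1 (SD, n = 5) at 10 µg/L. Pairs of arrays correlated across probes at r = 0.820 to 0.958, probes not being independent replicates.

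Estradiol production by ovary tissue fell with the dose score, with a wide spread at the lowest concentration. It averaged 0.431 ± 0.0882 ng/ml/12h in the controls (SD, n = 6), 0.298 ± 0.285 at 0.01 µg/L (n = 5), 0.363 ± 0.0896 at 0.1 µg/L (n = 5), 0.306 ± 0.136 at 1.0 µg/L (n = 6), 0.203 ± 0.110 at 10 µg/L (n = 5) and 0.196 ± 0.115 at 100 µg/L (n = 5). Estradiol is the main estrogen of the female fish and drives the liver to make vitellogenin, the egg yolk precursor. Across fish it fell with the dose score, with Pearson's r = -0.47 (permutation p = 0.00656, adjusted p = 0.0262) and Spearman's rho = -0.47 (permutation p = 0.0071, adjusted p = 0.0284). Without the 2 fish farthest from the median estradiol, r was -0.41. Single fish decided the calls: Pearson's did not pass without BPA 100 replicate C (-0.43) or D (-0.44), nor did Spearman's without these (-0.44 each) or without control replicate D (-0.43), E (-0.45) or F (-0.43). Within tank numbers 1, 2 and 3, rho was -0.34, -0.78 and -0.26, and none of these passed the threshold after adjustment over 12 values. Among exposed fish alone rho was -0.30 (permutation p = 0.132, adjusted p = 0.264). With tank means in place of fish, over 18 tanks, both calls just held. Pearson's r was -0.58 (permutation p = 0.0120, adjusted p = 0.0481) and rho -0.59 (permutation p = 0.0123, adjusted p = 0.0491).

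Set against the control, estradiol production was lower by a difference of -0.228 ng/ml/12h at 10 µg/L (95% interval -0.363 to -0.0934) and of -0.235 ng/ml/12h at 100 µg/L (95% interval -0.373 to -0.0967). In both groups 0 of 5 fish exceeded the control median. At 0.01 µg/L the difference of -0.133 ng/ml/12h depended on single fish. Without replicate B (0.789) it was -0.256 ng/ml/12h (exact permutation p = 0.00476, adjusted p = 0.0577). Without replicate D (0.0654) it was -0.0750 ng/ml/12h (exact permutation p = 0.586, adjusted p = 0.768). The differences with all fish and without replicate B lay within the 95% intervals at 10 and 100 µg/L, and the one without replicate D did not. These differences thus gave no clear order of the concentrations. At 10 and 100 µg/L the exact permutation p was 0.00866 for each, and the adjusted p of 0.0866 over 20 comparisons did not pass. None of the other 18 comparisons of a measure with the control passed. With tank means in place of fish, 3 tanks against 3 allow no exact p under 0.10.

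Plasma vitellogenin showed its highest mean at the highest concentration. It averaged 19.6 ± 9.53 mg/ml in the controls (SD, n = 6), 17.4 ± 7.74 at 0.01 µg/L (n = 5), 14.9 ± 5.90 at 0.1 µg/L (n = 5), 11.2 ± 4.96 at 1.0 µg/L (n = 6), 29.4 ± 10.6 at 10 µg/L (n = 4) and 33.9 ± 10.6 at 100 µg/L (n = 5). At 100 µg/L 5 of 5 fish lay above the control median, a difference of 14.3 mg/ml (95% interval 0.614 to 28.1, exact permutation p = 0.0498, adjusted p = 0.332), which did not pass. Across 31 fish the trend with the dose score gave Pearson's r = 0.42 (permutation p = 0.0191, adjusted p = 0.0381) and Spearman's rho = 0.36 (permutation p = 0.0462, adjusted p = 0.0925), so the call depended on the coefficient. It was lost with tank means in place of fish (Pearson's r = 0.51, permutation p = 0.0343, adjusted p = 0.0685, and rho = 0.37, permutation p = 0.141, adjusted p = 0.281, over 17 tanks). Pearson's also did not pass without BPA 0.01 replicate B (0.40), BPA 10 replicate B (0.40) or C (0.39), BPA 100 replicate A (0.39), C (0.38), D (0.37) or E (0.35), or control replicate C (0.39) or E (0.41), and Spearman's passed without control replicate A or B (0.42 each). Without the 2 farthest fish r was 0.30. Among the exposed fish alone rho was 0.50 (permutation p = 0.0113, adjusted p = 0.0453). Within tank numbers 1, 2 and 3 rho was -0.14, 0.67 and 0.21.

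Testosterone production and the gonadosomatic index did not follow the concentration beyond the spread between fish. Testosterone averaged 0.0814 ± 0.0715 ng/ml/12h in the controls (SD, n = 6). Means of the exposed groups ranged from 0.0728 ± 0.0446 at 1.0 µg/L (n = 6) to 0.220 ± 0.283 at 0.01 µg/L (n = 5). The latter mean rested on replicate A (0.714), without which the difference from the control was 0.0156 in place of 0.139 ng/ml/12h. At 10 µg/L 5 of 5 fish lay above the control median, a difference of 0.0873 ng/ml/12h (exact permutation p = 0.197, adjusted p = 0.447). Without control replicate A (0.218) this difference was 0.115 (exact permutation p = 0.00794, adjusted p = 0.159), which did not pass. Without BPA 10 replicate A (0.404) it was 0.0285 (exact permutation p = 0.510, adjusted p = 0.667). Testosterone's rho with the dose score was 0.22 (permutation p = 0.227, adjusted p = 0.302) and its Pearson's r 0.068 (permutation p = 0.731, adjusted p = 0.731). Without BPA 0.01 replicate A its Pearson's r was 0.29 (permutation p = 0.117, adjusted p = 0.156). The gonadosomatic index averaged 13.8% ± 5.23 in the controls (SD, n = 6) and between 10.9% ± 2.82 at 1.0 µg/L (n = 6) and 14.2% ± 4.56 at 0.01 µg/L (n = 5) in the exposed groups. Its rho was -0.18 (permutation p = 0.324, adjusted p = 0.324) and its Pearson's r -0.22 (permutation p = 0.233, adjusted p = 0.311). Within tank numbers 1, 2 and 3 rho was -0.0061, 0.75 and -0.23 for testosterone, and -0.45, 0.086 and -0.26 for the index.

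**Figure D1:**
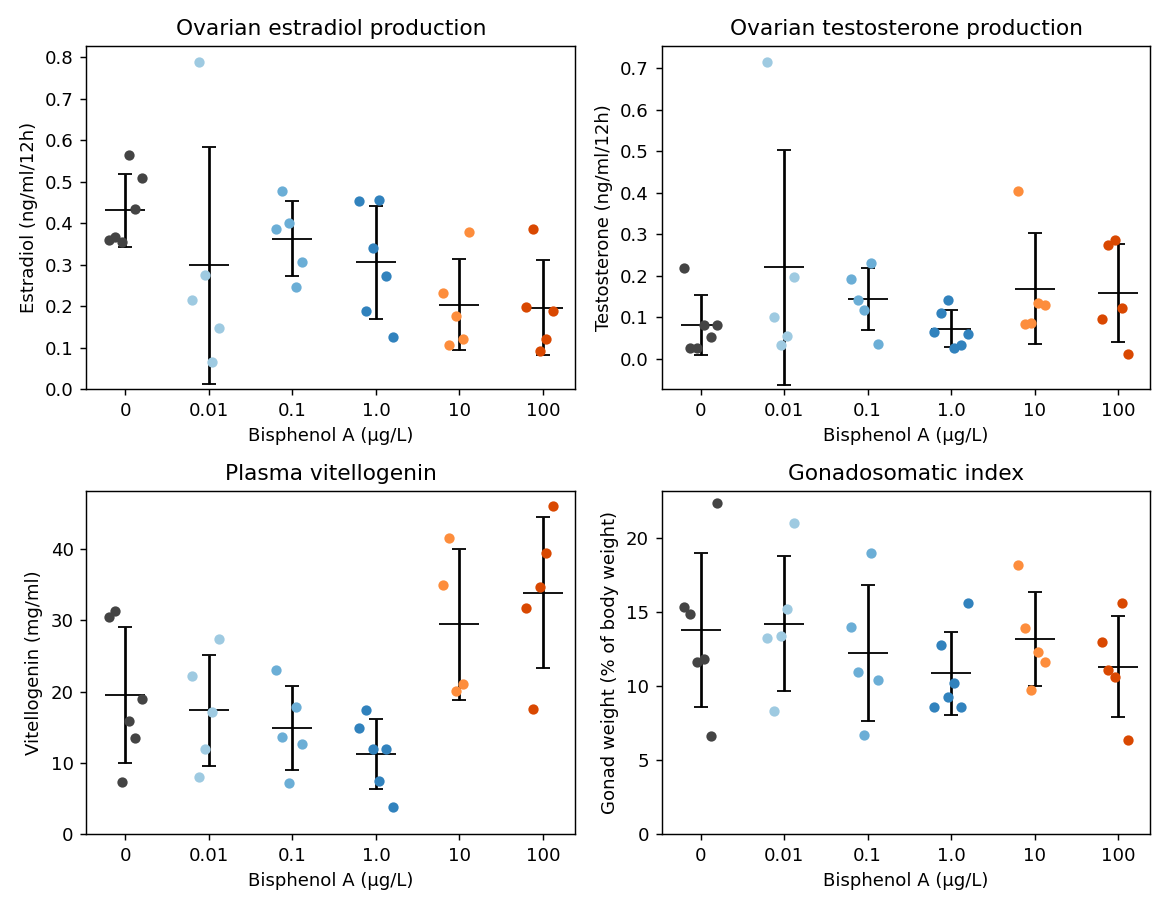
Estradiol and testosterone production (ng/ml/12h), plasma vitellogenin (mg/ml) and gonadosomatic index (% of body weight) against bisphenol A concentration (µg/L, groups evenly spaced); points are fish, wide marks the group means and bars 1 SD. Estradiol means ran from 0.431 in the controls to 0.196 at 100 µg/L, and vitellogenin means from 11.2 at 1.0 µg/L to 33.9 at 100 µg/L.

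Ovarian transcripts did not differ detectably between the groups. Of 11668 probes, 0 passed an adjusted p of 0.05 in limma's moderated F test over the 6 groups, and 576 had an unadjusted p under 0.05, where 583.4 would be expected with no difference. The mean of the exposed groups against the control gave 0 calls by limma, with 668 probes at an unadjusted p under 0.05. The dose trend gave 0 calls by limma, with 576 such probes. The lowest adjusted p was 0.673 in the F test, 0.216 for the exposed groups and 0.232 for the trend. With control replicates D and E left out, 1 probe passed the F test, and 1 passed without BPA 10 replicate A or BPA 100 replicate C. For the exposed groups 1 probe passed without control replicate A or B. In the authors' value table the F test called 2099 probes and the exposed groups 385, of which 384 were lower. On each array's own 75th percentile the F test still called 1617 of that table and the exposed groups 1.

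No single concentration differed from the control in any probe past the threshold. At an unadjusted p under 0.05 limma gave 414 probes at 0.01 µg/L, 369 at 0.1 µg/L, 776 at 1.0 µg/L, 1115 at 10 µg/L and 439 at 100 µg/L, with 0 calls after adjustment in each. The 1115 probes at 10 µg/L comprised 411 higher and 704 lower values. At 1.0 µg/L 3 probes passed without control replicate B. A lowest concentration with a transcript response could therefore not be named from these values. On simulated arrays 16% of 2-fold, 40% of 3-fold and 46% of 4-fold changes at 10 µg/L were recovered, so larger changes in single probes can have been missed. In the values deposited by the authors 4349 probes passed at 10 µg/L, 6 higher and 4343 lower, and 14 passed at 0.01 µg/L. After each array's own 75th percentile was subtracted from those values, 1464 passed at 10 µg/L, 1405 higher and 59 lower, and 78 passed at 1.0 µg/L.

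**Figure D2:**
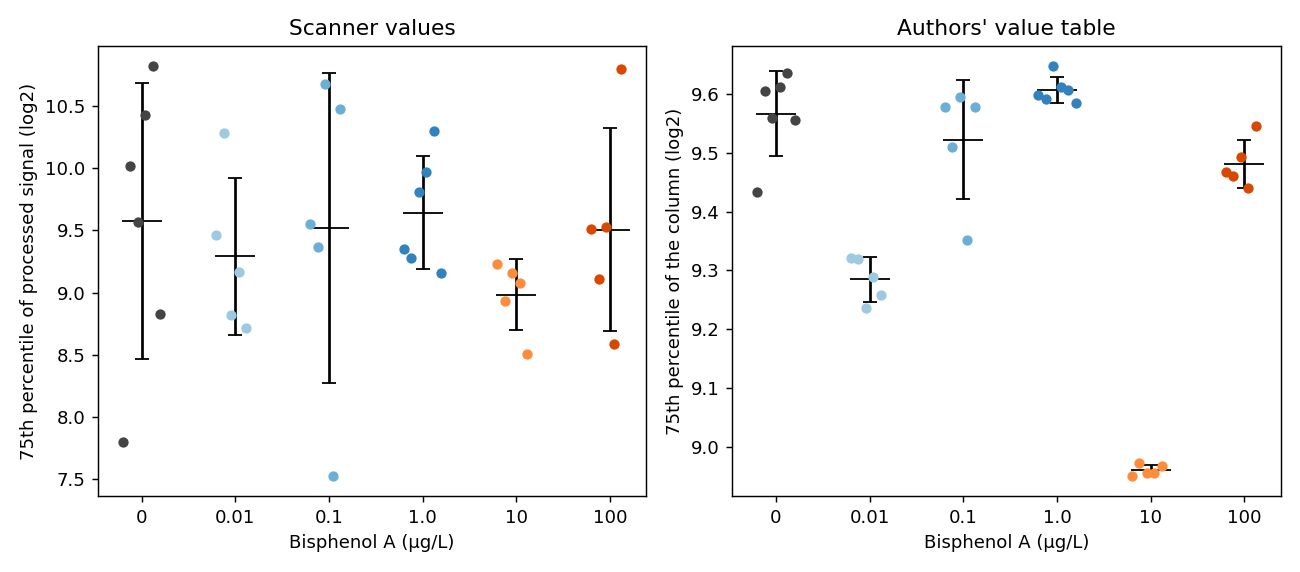
The 75th percentile of each array on a log2 scale against bisphenol A concentration (µg/L, groups evenly spaced), from the scanner values and from the authors' value table; points are arrays, wide marks the group means and bars 1 SD. In the value table the 5 arrays at 10 µg/L lie between 8.95 and 8.97 and the 6 control arrays between 9.43 and 9.64.

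Profiles of log2 differences from the control correlated between concentrations at r = 0.34 to 0.58 across 10459 probes in the 10 pairs, with a median of 0.51. For unchanged groups, deviations of all fish from their group means were shuffled among the groups. The simulated controls of a draw were thus shared by its pairs but came from fish of any group. These draws gave a median r of 0.47, and 36 of 100 were as high. The median covariance was 0.160 against 0.144 in the simulation, with 39 of 100 draws as high. When each member of a pair was set against a different set of 3 controls, the median r was -0.047.

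Some transcripts moved with ovary size, though this could not be told apart from array brightness. Within dose groups 1122 of 11668 probes had a slope on the gonadosomatic index past an adjusted p of 0.05 in limma, 304 rising and 818 falling with a larger ovary. The balance of directions depended on processing: 4956 of 5314 rose with normexp, 2299 of 3494 without a filter and 244 of 400 with the filter on all 32 arrays. The median slope of the rising probes corresponded to 1.40-fold over 5 percentage points of the index, and that of the falling probes to 0.621-fold. Of the rising probes 256, and of the falling probes 172, were well above background on all 32 arrays. The index also moved with array brightness: its Pearson's r with the log2 75th percentile was -0.70 (permutation p = 1e-05, the smallest the permutations can give) and Spearman's rho -0.71 (permutation p = 3e-05), and r was -0.73 without the 2 farthest fish. With brightness as a covariate, chosen after seeing the data, 0 probes passed in limma.

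The number of such probes rested on a few fish. It was 18 without control replicate F, 28 without control replicate E, 298 without BPA 100 replicate E 325 without BPA 0.01 replicate B, 681 without BPA 100 replicate D, 740 without BPA 0.1 replicate C and 1724 without BPA 10 replicate A. Without control replicates D and E it was 4. With tank number as a block 728 probes passed and with slide as a block 1801. With the array letter as a replicate block, which carries parts of both, 33 passed. Within tank numbers 1, 2 and 3, the slope of 85.8%, 97.9% and 100% of the 1122 probes had the same sign as in all fish, and on slides 1 to 4 that of 100%, 95.5%, 92.8% and 93.0%. These probes were chosen on the same fish.

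Among the rising probes, UF_Ppr_AF_115760 (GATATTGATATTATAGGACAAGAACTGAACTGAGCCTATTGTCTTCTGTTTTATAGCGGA) had the steepest slope, 0.39 ± 0.074 log2 units per percentage point (SE, limma adjusted p = 0.00683), but was well above background on 8 arrays. Across 32 fish its Pearson's r with the index was 0.70 (permutation p = 5e-05) and rho 0.49 (permutation p = 0.00482), with r = 0.54 without the 2 farthest fish. Its log2 values lay at -2.67 to -1.97 in BPA 0.01 replicate E, BPA 0.1 replicate D, BPA 1.0 replicate F and control replicates B and F. In all other fish they lay at -6.16 or lower. UF_Ppr_AF_109694 (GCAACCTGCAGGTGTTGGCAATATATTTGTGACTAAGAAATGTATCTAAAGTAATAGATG) had a slope of 0.30 ± 0.080 (SE, limma adjusted p = 0.0242), and 0.18 (limma adjusted p = 0.126) without control replicate E. Among the falling probes, UF_Ppr_AF_105833 (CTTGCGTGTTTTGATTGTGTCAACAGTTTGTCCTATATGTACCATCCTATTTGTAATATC) had a slope of -0.41 ± 0.096 (SE, limma adjusted p = 0.0162). UF_Ppr_AF_105221 (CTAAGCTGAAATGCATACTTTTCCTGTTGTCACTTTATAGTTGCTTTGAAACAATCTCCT) had a slope of -0.35 ± 0.10 (SE, limma adjusted p = 0.0337), and with tank number as a block its adjusted p was 0.0599. Values of UF_Ppr_AF_105833 were 0.32 or higher or -2.62 or lower in every fish. Those of UF_Ppr_AF_109694 were -7.86 in control replicate E, -6.13 in BPA 0.1 replicate C and -1.41 or higher in the others. The slopes of UF_Ppr_AF_115760, UF_Ppr_AF_109694 and UF_Ppr_AF_105833 thus describe 2 levels of signal between fish more than a graded change. Single fish decided some calls of the 4 probes. Without control replicate F none of the 4 passed, with slopes of 0.37, 0.32, -0.44 and -0.32 in the order above. Without control replicate E UF_Ppr_AF_105833 (-0.38) and UF_Ppr_AF_105221 (-0.36) did not pass either. UF_Ppr_AF_109694 did not pass without BPA 0.1 replicate C (0.23). UF_Ppr_AF_105221 did not pass without BPA 0.01 replicate B (-0.35) or E (-0.31), BPA 0.1 replicate C (-0.31), or BPA 100 replicate D (-0.33) or E (-0.32). With the letter as a replicate block none of the 4 passed, with slopes of 0.38, 0.32, -0.45 and -0.26. Sizes depended on processing: in the same order the slopes were 0.21, 0.23, -0.27 and -0.12 with normexp and 0.13, 0.23, -0.30 and -0.17 in the authors' value table. The sign of each of the 4 correlations with the index, taken without dose-group terms, was the same within all 4 slides and all 3 tank numbers. These probes were chosen on the same fish, so this is no separate support.

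**Figure D3:**
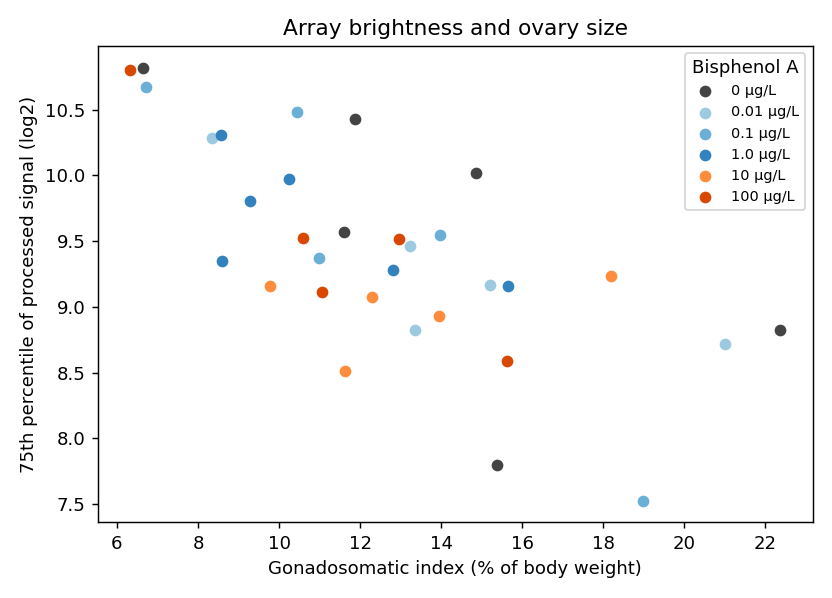
Log2 75th percentile of the processed signal of each array against the gonadosomatic index of its fish (% of body weight), coloured by bisphenol A concentration. Fish with larger ovaries had dimmer arrays, with r = -0.70 over 32 fish.

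Within dose groups no transcript passed for the hormones or vitellogenin in the reported fit, but for both hormones calls appeared under other settings. Estradiol production gave 0 calls in limma within dose groups, with 520 probes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0540. Leaving out BPA 0.01 replicate A or E, BPA 1.0 replicate A, or BPA 10 replicate A or D gave 1 call. With tank number as a block 1 probe passed, described here after its values were seen. Its slope was 1.00 ± 0.14 log2 units per doubling of estradiol (SE, limma adjusted p = 0.00217), against 0.89 ± 0.16 (SE, limma adjusted p = 0.0540) without the block, and it was well above background on 17 arrays. Testosterone production gave 0 calls by limma, with 1875 probes at an unadjusted p under 0.05, of which 1405 fell with higher testosterone. With array weights 1144 probes passed for testosterone, and 399 passed without control replicates D and E. Vitellogenin gave 0 calls by limma over 31 fish, with 871 probes at an unadjusted p under 0.05.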

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

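The tests of whole tanks, within tank numbers too, of dim probes, of the lower calls alone and of the brightness of the BPA 10 arrays were chosen only after the result was seen.

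In 13 of 66 groups of values 1 sample lay far from the rest of its group, where chance gives about 1 in 20 for normally distributed values. Testosterone and the 75th percentile were taken here without a log2 scale. Skewed values can add such cases, which was not tested. Of these, 7 came from the 4 named probes, which were picked for steep slopes, so part of the excess follows from that choice. Testosterone production was high in BPA 0.01 replicate A (0.714 ng/ml/12h), BPA 10 replicate A (0.404) and control replicate A (0.218), each from tank number 1. The 75th percentile of the processed signal stood out in BPA 100 replicate E (1782), and the number of probes well above background in BPA 0.01 replicate B (11106) and BPA 1.0 replicate E (11518). On the log2 scale over the 75th percentile, UF_Ppr_AF_115760 stood out in BPA 0.01 replicate E (-2.22), BPA 0.1 replicate D (-1.97) and BPA 1.0 replicate F (-2.36). UF_Ppr_AF_109694 was low in control replicate E (-7.86). UF_Ppr_AF_105833 was high in BPA 0.01 replicate B (2.14) and BPA 10 replicate C (0.32) and low in BPA 1.0 replicate B (-5.44).

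Probes that followed the gonadosomatic index numbered 1122, and 2 of 100 permutations of the index within dose groups gave as many, the real one included, with 1946 the highest of the others. When whole tanks were moved among tanks with as many fish, 1 of 100 did, the real one, with 823 the highest of the others. With tanks moved within tank numbers and tank number as a block, again only the real one of 100 reached its 728 probes (highest other 307). Counts this high were thus rare under these 3 ways of shuffling. Chance is not excluded, since a random shuffle within dose groups gave more probes than the real index. Of the 6130 probes well above background on all 32 arrays 6.98% passed, so the called probes were not all dim. This does not decide whether background subtraction accounts for the pattern. Each array was scaled on a percentile of its background-subtracted signal, so the subtraction can shift bright probes as well. The directions also changed with the background correction: 304 of 1122 called probes rose in the reported values and 4956 of 5314 with normexp. With array brightness as a covariate the median slope of the called probes was 0.447 of its value without, the median slope falling from 0.129 to 0.0560 and the median SE growing from 0.0356 to 0.0483, so array brightness may carry a large part of the pattern. Brightness moves with ovary size itself, so a change of the ovary's RNA with its growth stays open, and no biological explanation was tested.

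Lower values at 10 µg/L in the authors' value table numbered 4343. Between dose groups lay 93.9% of the variance of the 75th percentile in that table and 8.03% in the scanner values. The arrays at 10 µg/L lay at 8.95 to 8.97 in the table and at 8.51 to 9.23 in the log2 scanner values. At 0.01 µg/L the arrays lay at 9.24 to 9.32 in the table and at 8.72 to 10.28 in the log2 scanner values. The table thus held the arrays of each of these groups levelled with each other and not across groups. After each array's own percentile was subtracted, calls in either direction came to 33.7% of those before. This lies between the bounds set beforehand, so the share of calls by itself does not decide whether separate normalization of the groups accounts for them. Of the lower calls 1.36% stayed lower, which does not decide it either, since this step removes a real lower level of most probes as well. In the scanner values the BPA 10 arrays were the dimmest group, with a mean 75th percentile of 513 against 680 to 943 in the other groups. Still, 2 control arrays were dimmer than the brightest of them and lay above all of them in the table. The dimness of single arrays therefore does not account for the lower values. A lower signal of the group as a whole goes with them. The groups dimmest on average in the scanner values, at 10 µg/L (513) and 0.01 µg/L (680), also lay lowest in the table. The table thus kept the mean brightness of these groups, and what made it low at 10 µg/L was not tested. Before that step the mean difference from the control was -0.083 at the 10th percentile of the probes and -0.593 at the 75th percentile. Subtracting the 75th percentile thus lifts dim probes at 10 µg/L against the control, and the 1405 higher calls can follow from the step itself. Whether they do was not tested probe by probe. An effect of bisphenol A at 10 µg/L cannot be told apart from scaling in that table, and the scanner values gave 0 calls.

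Fish of one tank resembled each other. Deviations from the dose mean correlated at -0.10 over 15 pairs from one tank and at -0.26 over 55 pairs of one dose from different tanks, a difference that shuffling tanks within doses gave with a one-sided permutation p of 0.00396. Over pairs on different slides the difference was 0.207, which argues against shared slides. With brightness and the gonadosomatic index as covariates a share of 0.633 of it was left, above the bound of 0.5 set beforehand. A shared water, holding or sampling history of a tank stays open and was not tested.

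For the comparisons of groups, the number of probes at an unadjusted p under 0.05 was set against splits of the fish, 100 for each with the real one included. As many probes as the real 576 of the F test came from 39 splits, with 1591 the highest other. For the exposed groups (668) it was 30 splits, highest other 2808, and for the dose trend (576) 41 splits, highest other 2344. Against the control it was 68 splits for 0.01 µg/L (414, highest other 3124), 77 for 0.1 µg/L (369, highest other 2526), 22 for 1.0 µg/L (776, highest other 2620), 20 for 10 µg/L (1115, highest other 2808) and 77 for 100 µg/L (439, highest other 3108). Chance could not be excluded for any of them under these splits, which moved single fish and did not keep fish of one tank together. Other splits reached several times the real numbers. Some also gave probes past an adjusted p of 0.05 in limma, from 5 splits for the dose trend to 11 for the F test. The most such probes in a split were 971 for 0.01 µg/L and 1062 for 100 µg/L. This may point to a structure of the samples apart from dose or to probes that vary together in few fish, and was not tested.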

How the results depend on the processing

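The settings with array brightness, with the value table on each array's own percentile, without control replicates D and E, within tank numbers and of trends without 1 fish were chosen after seeing the data. Where values moved, the cause was not tested unless stated.

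The 0 calls of the dose trend and of 0.1 and 100 µg/L against the control held under every alternative run. For the other comparisons of groups, calls appeared in the authors' value table (2099 in the F test, 385 for the exposed groups, 14 at 0.01 µg/L, 4349 at 10 µg/L), in that table on each array's own percentile (1617, 1 for the exposed groups, 78 at 1.0 µg/L, 1464 at 10 µg/L) and without control replicates D and E (1 in the F test). The median log2 difference of all probes at 10 µg/L from the control was -0.079 in the reported values, -0.43 in the value table (a shift of -0.35), 0.17 in that table recentred (0.24), 0.21 with normexp (0.29) and -0.018 with quantile normalization (0.060). At 0.01 µg/L the value table, that table recentred and normexp shifted it by -0.19, 0.10 and 0.13, and for the exposed groups the value table did by -0.12. Leaving out 1 fish gave 0 to 1 calls in the F test (1 without BPA 10 replicate A or BPA 100 replicate C) and for the exposed groups (1 without control replicate A or B), and 0 to 3 at 1.0 µg/L (3 without control replicate B).

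For estradiol 1 probe passed with slide, tank, tank number or the replicate letter as a block, 3 without dose-group terms, and 0 to 1 with 1 fish left out (1 without BPA 0.01 replicate A or E, BPA 1.0 replicate A, or BPA 10 replicate A or D). For testosterone 1144 passed with array weights and 399 without control replicates D and E.

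Against 1122 probes for the gonadosomatic index (304 rising), 5314 (4956 rising) passed with normexp, 3494 (2299 rising) without a filter, 400 (244 rising, 6130 probes tested) with the filter on all arrays, 1801 with slide as a block, 728 with tank number as a block, 1868 with array weights, 517 without dose-group terms, 0 with brightness as a covariate and 4 without control replicates D and E. The recentred value table gave 770 (377 rising). Leaving out 1 fish gave 18 to 1724: 18 without control replicate F, 28 without control replicate E, 298 without BPA 100 replicate E, 325 without BPA 0.01 replicate B, 681 without BPA 100 replicate D, 740 without BPA 0.1 replicate C and 1724 without BPA 10 replicate A. Of 14 alternatives, UF_Ppr_AF_105221 lost its call in 9, UF_Ppr_AF_109694 and UF_Ppr_AF_105833 in 4 each and UF_Ppr_AF_115760 in 3, with the sign kept. With brightness as a covariate these slopes were -0.50, 0.18, -0.40 and 0.39, none called. The array letters (A to F) as a replicate block left 33 probes. Fish of different groups with the same letter correlated at 0.043 on average (-0.35 to 0.46), against -0.0090 for other letters, and 7 of 32 fish were closest to their own letter. The letters run together with tank number and slide in part (each A in tank number 1 on slide 4, each E in tank number 3 on slide 1), so this block takes up shares of both, and it ended the calls of the 4 named probes. Why it left fewer probes than either alone was not tested. Neither block changed a call of a dose comparison.

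Estradiol's rho with the dose score missed the threshold among exposed fish (-0.30) and within tank numbers 1 (-0.34), 2 (-0.78) and 3 (-0.26), where fewer fish were left, and vitellogenin's passed among exposed fish (0.50). Without 1 fish estradiol's rho ranged from -0.55 to -0.43 and missed it in 5 of 32 settings (BPA 100 replicates C and D, -0.44 each, and control replicates D, -0.43, E, -0.45, and F, -0.43) and vitellogenin's ranged from 0.30 to 0.42 and passed without control replicate A or B (0.42 each). Within tank numbers the sign turned for the gonadosomatic index (0.086, number 2), testosterone (-0.0061 and -0.23, numbers 1 and 3) and vitellogenin (-0.14, number 1), none of them called. With tank means the difference from the control turned for the index at 10 µg/L (0.213) and testosterone at 1.0 µg/L (0.00825). Leaving out 1 fish turned the index at 0.01 µg/L (-1.25 to 2.16), 0.1 µg/L (-3.26 to 0.149) and 10 µg/L (-2.05 to 1.09), testosterone at 1.0 µg/L (-0.0222 to 0.0188) and vitellogenin at 0.01 µg/L (-4.70 to 0.158). The median r between dose profiles was -0.047 with split controls, which removes the shared controls. The gene list tests were not run, since probes had no gene names. Dim signal limits the probes tested: 6130 of 11668 were well above background on every array.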

Other observations

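The test of testosterone by tank number was chosen only after the result was seen.

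Testosterone production was highest in tank number 1. Its geometric mean was 0.175 ng/ml/12h in tank number 1 (10 fish), 0.0799 in number 2 (10 fish) and 0.0642 in number 3 (12 fish). Shuffling single fish within dose groups gave a permutation p of 0.0103. This treats fish of one tank as independent, though they share the tank number, and whole tanks were not shuffled. Fish were added to tanks in a stagger by tank number, so a time effect may be a candidate explanation, but other differences between tank numbers were not separated from it.

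The fall of estradiol production with the dose score was not weakened by a linear adjustment for ovary size. The partial correlation of log2 estradiol with the dose score given the gonadosomatic index was -0.53 (permutation p = 0.00191), against -0.44 without it (permutation p = 0.0111). These permutations moved single fish and did not keep fish of one tank together. The fall itself depended on single fish, as given above.

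Among 6 pairs of fish measures, none correlated past an adjusted p of 0.05. Estradiol and vitellogenin, both on a log2 scale, gave Pearson's r = -0.38 (permutation p = 0.0370, adjusted p = 0.153) and rho = -0.46 (permutation p = 0.00956, adjusted p = 0.0574) over 31 fish, with r = -0.37 without the 2 fish of most extreme estradiol. Within dose groups r was -0.24 (permutation p = 0.231), weaker than across them. Within tank numbers 1, 2 and 3 r was -0.46, -0.79 and -0.093.

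Probes whose design names share a contig prefix were expected to have similar slopes on the gonadosomatic index. Over 1798 pairs from 1085 prefixes the median absolute difference of slope was 0.0662, and 25.6% of random pairings had a higher one. Probes of one prefix were thus no more alike than others in this slope, and their values across fish were not compared.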
